A study of Mus musculus with 10 samples.

How the data were processed

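RNA was sequenced from oocytes sorted by green fluorescence (an Oct4-EGFP transgene marks germ cells) and by exclusion of dead cells from mouse fetal ovaries at E16.5, per the labels' protocols. The 10 libraries fall into 2 genotypes of 5 libraries each, Taf4b-heterozygous and Taf4b-deficient, and each carries a litter date, of which there are 3, per the labels. Nothing in the labels says whether the 5 libraries of a genotype came from separate embryos, so p-values measure the spread between these libraries, part of which may be technical.

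The authors deposited a table of whole-number counts per gene, made with Trim Galore 0.5.0, HISAT2 2.1.0 and featureCounts of Subread 1.6.2 on GRCm38, per the submitters' processing notes. Strand and multi-mapping settings of the counting are not given in the sources used here, so genes that share reads with near-identical copies, and overlapping or antisense genes, are uncertain. The authors also deposited TPM, a length-scaled relative expression value, per gene from StringTie 1.3.3b, per the submitters' processing notes. A further table is the authors' deposited comparison from DESeq2, with a log2 fold change, its standard error, a score (the Wald statistic), a mean normalized count, a p-value and an adjusted p-value per gene, per the file headers. Its sign was read as deficient over heterozygous from Taf4b, and its 31181 rows all have a total count of at least 10. Every column with per-library values was matched to a sample by genotype and replicate number. Of the 55536 genes in the count table, 382 had no symbol, and these took 0.0632% to 0.0945% of the counts of a library.

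The counts as deposited were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood test on genotype alone, with TMM (trimmed mean of M-values) scaling and edgeR's expression filter, which left 19244 genes. P-values were adjusted by Benjamini-Hochberg and called under 0.05. CPM values, the counts scaled to a common library size, use the TMM-scaled library sizes. Standard errors (SE) of fold changes are the size of the fold change divided by the square root of its F statistic. Gene lists were tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01, for lists with at least 5 tested members. An estimated correlation and fry were run beside it. The lists held 661 genes in 28 lists, of which 651 were found and 589 tested. They covered germ cell biology (TFIID subunits, meiotic entry, synaptonemal complex and meiotic cohesin, meiotic recombination, DNA damage response and repair, oocyte growth and folliculogenesis, primordial germ cell and pluripotency, pan-germ cell, male fetal germ cell, premature ovarian insufficiency, chromatin modifiers, DNA methylation, general transcription and promoter factors, cell cycle and mitosis, apoptosis and p53 targets, oxidative phosphorylation), other cell types and library quality. The ratio of X-linked to autosomal expression was the median TPM of X-linked genes over that of autosomal genes, among genes with a TPM of at least 1, compared by a two-sided exact permutation test.

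The design, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names Taf4b first, and Xist as a value. Among called genes with a symbol and a mean log2 CPM of at least 1, it takes the 6 with the largest change and the 4 with the smallest adjusted p in each direction. From each list it takes up to 3 called members with the smallest adjusted p or, with none called, the tested member with the highest mean. Because edgeR called no gene, the rule was also applied to the calls of the authors' deposited table, a step chosen after the data were seen. Of the genes the rule names, 1 is not reported here.

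The alternatives were other scalings and low-count filters, DESeq2 1.42.0, limma voom with quality weights, limma on log2(TPM + 1) and log2(TPM + 0.1), litter date or replicate number in the model, and each library or litter date left out. After the data were seen, 4 more were added: a 3-level grouping of the libraries that rebuilds the authors' deposited fold changes, leaving out each of its levels, 2 surrogate variables from sva 3.50.0, and edgeR with bias-adjusted deviances. That grouping was found by solving for the weights of the libraries in the deposited fold changes. DESeq2 refitted with it as a covariate matched all 31181 deposited log2 fold changes to within 0.00555 and gave the same number of calls, 1172. With the litter dates of the labels, the refit gave 1824 calls and a median difference in log2 fold change of 0.248.

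The test was tested on simulated counts made from these libraries' means and sizes. Of 100 genes changed 2-fold, 15% were recovered, and of 100 genes changed 4-fold, 78%, among 18766 genes tested. Of 18526 unchanged genes, 7 were called. Simulated genes were drawn independently, with the same spread in both genotypes and no grouping of libraries. The real libraries differ from that, so these shares may not hold for them.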

Results

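Gene expression was measured by RNA sequencing in sorted mouse oocytes at E16.5, late in fetal life, in 5 Taf4b-heterozygous and 5 Taf4b-deficient libraries. TAF4b is a gonad-enriched subunit of TFIID, the general transcription factor that binds core promoters. The design asks which oocyte transcripts depend on Taf4b as oocytes pass through meiotic prophase. Total counts ran from 16707200 to 26983600 per library, each rounded, from 18174900 to 26983600 in heterozygous and from 16707200 to 23680000 in deficient libraries. Y-linked genes of a fixed list had 0 to 2 counts per library, and none was tested.

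The heterozygous libraries differed from one another more than the deficient libraries did. Correlations of log2 CPM across genes ran from 0.902 to 0.978 between heterozygous libraries and from 0.959 to 0.980 between deficient libraries. For pairs of opposite genotype they ran from 0.907 to 0.974. The median was 0.941 for these pairs, 0.941 within heterozygous and 0.967 within deficient libraries. The gene lists whose levels spread most among heterozygous libraries ranged over 4.67 on the log2 scale in heterozygous and 3.90 in deficient libraries for erythroid cells, 2.57 and 2.26 for endothelial cells, 2.21 and 1.12 for mitochondrially encoded genes, 1.73 and 1.36 for histones, 1.496 and 0.34 for male fetal germ cells, 1.44 and 0.57 for ribosomal proteins, 1.37 and 0.31 for oocyte growth, and 1.34 and 0.67 for synaptonemal complex and meiotic cohesin. The range of meiotic entry was 0.96 and 0.73. Some lists spread more among deficient libraries, at 0.51 and 1.56 for surface epithelium, 0.66 and 1.54 for macrophages and 0.26 and 0.51 for chromatin modifiers. Pregranulosa cells, ovarian stroma and pan-germ cell genes did so by less. The genes that follow were chosen after their values were seen. Stra8, which drives entry into meiosis, was at 965 CPM in heterozygous 1 and at 10.3 CPM in heterozygous 5. Sohlh1, a transcription factor of early oocyte growth, was at 0.192 CPM in heterozygous 1, 9.30 CPM in heterozygous 2, 7.18 CPM in heterozygous 3, 149 CPM in the library labelled heterozygous 4 and 231 CPM in heterozygous 5. Nobox, another oocyte transcription factor, was at 84.8 and 166 CPM in those last libraries and at 10.1 to 16.9 CPM in the other heterozygous libraries. In deficient libraries Sohlh1 lay between 0.419 and 1.58 CPM, and Nobox between 3.48 and 7.25 CPM. The alpha-globin gene Hba-a1 was at 260 CPM in the library labelled heterozygous 4, 798 CPM in heterozygous 5 and 590 CPM in deficient 5, against 24.0 to 102 CPM in the other libraries. The libraries high for Hba-a1 are the third level of the grouping that rebuilds the authors' deposited fold changes. That level holds 2 heterozygous libraries and 1 deficient library, so it and the wider heterozygous spread were not told apart. Heterozygous 3 stood apart on the second principal component and had 0.853% of its counts on mitochondrial genes, the lowest share of all libraries.

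**Figure D1:**
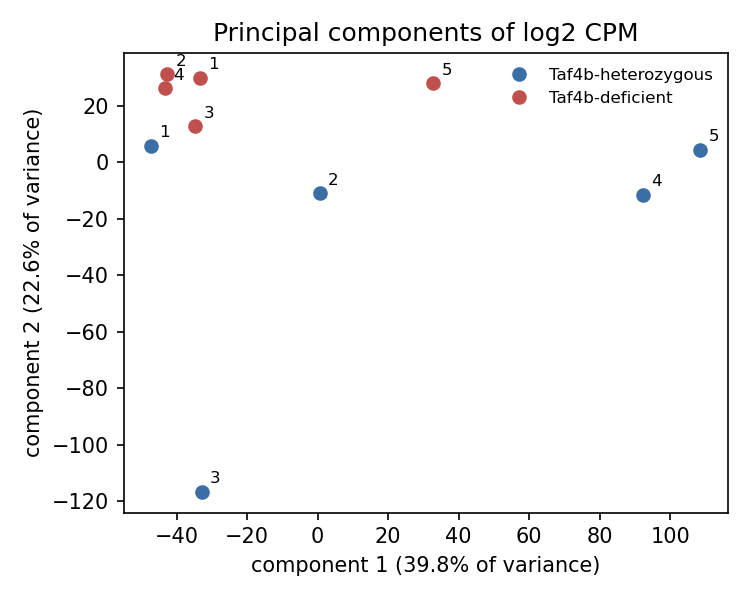
Principal components of log2 CPM, with component 1 (39.8% of variance) on the horizontal and component 2 (22.6%) on the vertical axis; points are libraries, numbered by replicate and coloured by genotype. Scores on component 1 are 92.3 for the library labelled heterozygous 4, 108 for heterozygous 5, 32.8 for deficient 5 and 0.595 for heterozygous 2, and negative for the others, and heterozygous 3 lies apart on component 2.

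**Figure D2:**
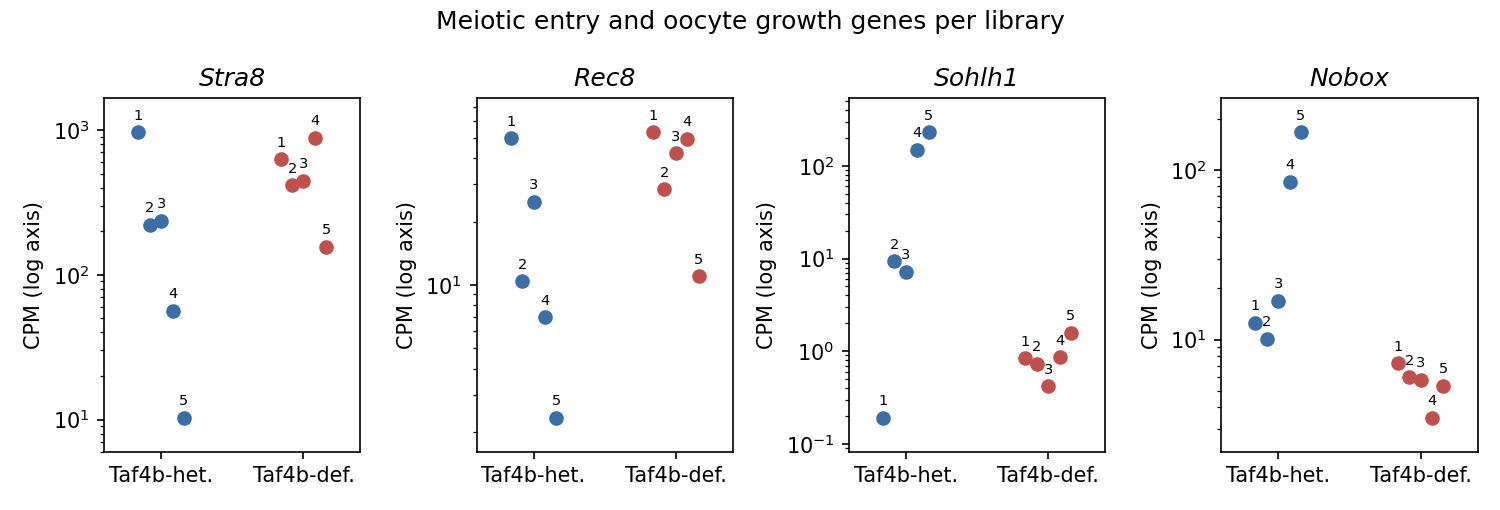
CPM of Stra8, Rec8, Sohlh1 and Nobox per library on log axes; points are libraries, numbered by replicate, with 5 per genotype. Sohlh1 spans 0.192 to 231 CPM among heterozygous and 0.419 to 1.58 CPM among deficient libraries.

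Taf4b itself (ENSMUSG00000054321, GRCm38 chromosome 18, 14783245 to 14900359, plus strand) was at 174 ± 101 CPM (SD, n = 5) in heterozygous and 74.9 ± 9.86 CPM (SD, n = 5) in deficient libraries. Heterozygous 1, 2, 3 and 5 were at 271, 290, 142 and 101 CPM, above every deficient library. The library labelled heterozygous 4 was at 65.7 CPM, within the deficient range of 58.2 to 81.7 CPM, so Taf4b does not check its label. The log2 fold change was -1.22 ± 0.35 (SE), with an adjusted p of 0.155 by edgeR's quasi-likelihood test (0.0361 with the deposited grouping in the model), and without the library labelled heterozygous 4 it was -1.42. By litter date of the labels, the log2 differences were -1.80, -0.26 and -0.62 in date order, each from 1 or 2 libraries per genotype. These dates match the grouping behind the authors' deposited table in 6 of 10 libraries, and by level of that grouping the differences were -1.74, -1.40 and -0.49. In the authors' deposited table Taf4b had a log2 fold change of -1.29 and an adjusted p of 0.000152. The count covers the whole gene, and the part altered by the mutation was not analysed here.

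**Figure D3:**
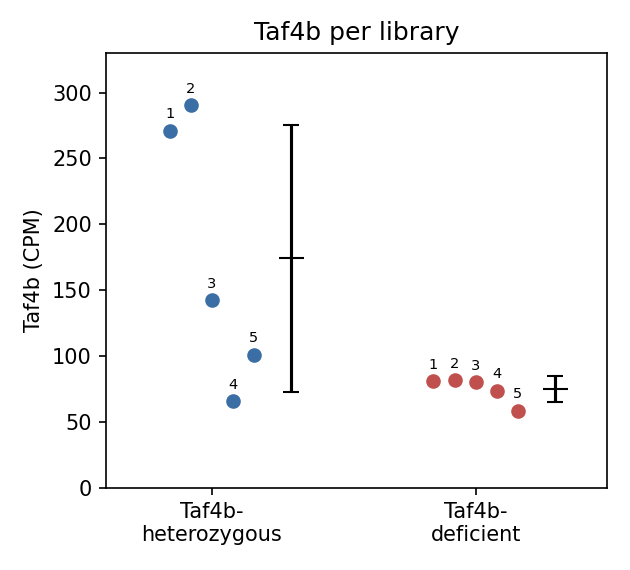
Taf4b in CPM per library by genotype; points are libraries, numbered by replicate, and bars are the mean with SD of 5 libraries. Deficient libraries sit between 58.2 and 81.7 CPM, and the library labelled heterozygous 4 lies among them at 65.7 CPM.

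At the level of single genes, no gene passed the threshold between genotypes by edgeR's quasi-likelihood test. Of 19244 genes tested, 0 were called and 3190 had an unadjusted p under 0.05, with a smallest adjusted p of 0.0871 for Trim52. DESeq2 called 643 genes, limma voom with quality weights 510, and limma on log2(TPM + 1) 0. The count rested on a single library: without heterozygous 1, edgeR called 606 genes, of which 280 were higher and 326 lower in deficient libraries. Of these 606, 452 are also called in the authors' deposited table, which was made from the same counts. That overlap is therefore no independent support. Of 77 genes reported by the rule for named genes besides Taf4b, 26 were called without heterozygous 1, namely Trim52, H1fx, Gm7067, Gm24270, Gm11815, Sohlh1, C87487, 2310003L06Rik, Gm44113, Itih2, Pramel3, Magea6, Gm13269, Kmt2b, Suz12, Dot1l, Tle6, Lin28a, Pmaip1, Uhrf1, Eif2b4, Lars2, Nfyb, Hist1h1a, Jund and Fst. With the deposited grouping as a covariate, chosen after the data were seen, edgeR called 104 genes, 71 higher and 33 lower. Of the 77, that fit called 16 with adjusted p from 0.0256 to 0.0382, namely Trim52, H1fx, H19, Gm7067, Gm24270, Nav3, Pamr1, Gm11815, Pramel3, Magea6, Gm13269, Kmt2b, Suz12, Dot1l, Mki67 and Hist1h1a. In 680 genes (3.53%) the genotypes did not overlap, and 373 of these were higher in deficient libraries. The share by chance is 0.794% as a mean over all splits of the libraries. Genes vary together, so a single split can lie far from that mean. No other splits were counted for this share, so chance is not excluded.

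The authors' deposited table calls 1172 genes, 572 higher and 600 lower in deficient oocytes. Of the 1150 that were tested here, 1149 had the same sign in the edgeR fit and 1058 an unadjusted p under 0.05. Both fits use the same counts, so this overlap is no independent support for the calls. All genes named from here to the gene lists were picked from the authors' deposited table, and their CPM and log2 fold changes are from the present counts and the edgeR fit on genotype alone, in which none passed the threshold. Trim52, the gene with the smallest p in the edgeR fit (chromosome 14, 106106198 to 106135859), was at 93.4 ± 11.95 CPM (SD, n = 5) in heterozygous and 40.8 ± 4.05 CPM (SD, n = 5) in deficient libraries, lower in 5 of 5, with a log2 fold change of -1.19 ± 0.16 (SE). The linker histone gene H1fx was at 4.78 ± 2.62 and 21.5 ± 8.96 CPM (log2 fold change 2.17 ± 0.40, SE), and the imprinted noncoding RNA H19 at 31.5 ± 8.81 and 64.3 ± 15.4 CPM (1.03 ± 0.23). Deficient libraries were above all heterozygous libraries in 5 of 5 for both. Gm7067 and Gm24270, annotated as a microRNA gene, had log2 fold changes of 2.42 ± 0.49 and 1.86 ± 0.31. Gm24270 was at 7.61 CPM in heterozygous 3, 16.3 to 27.7 CPM in the other heterozygous and 42.1 to 81.2 CPM in deficient libraries. Its reads may come from ribosomal RNA, which was not tested here. Nav3, Pamr1, Cdh26 and Ces1c are among the largest rises in the authors' deposited table, but their SD among deficient libraries was near or above their mean, for example 7.33 ± 7.36 CPM for Nav3, and Ces1c, Pamr1 and Cdh26 turned in direction under some alternatives.

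The largest falls in the authors' deposited table were in Gm11815, Sohlh1, C87487, 2310003L06Rik, Gm44113 and Itih2. Sohlh1 was at 79.3 ± 105 CPM in heterozygous and 0.886 ± 0.427 CPM in deficient libraries, a log2 fold change of -6.46 ± 1.36 (SE), and its value in heterozygous 1 lay below every deficient library. With the deposited grouping in the model it was -3.70. Gm11815 and C87487 had log2 fold changes of -6.50 ± 1.53 and -4.69 ± 1.17, with SDs above their heterozygous means. The lower genes with the smallest adjusted p after Trim52 were Pramel3, Magea6 and Gm13269. Pramel3 and Magea6, X-linked members of multigene families expressed in the germ line, were at 11.8 ± 8.54 and 14.8 ± 8.63 CPM in heterozygous and at 1.91 ± 0.76 and 3.46 ± 1.54 CPM in deficient libraries, lower in 5 of 5. Reads of such families can be split between copies, so their values are uncertain.

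Of 27 gene lists tested, camera called 9 with the preset correlation, 4 higher and 5 lower in deficient libraries. With an estimated correlation 0 were called, with adjusted p from 0.573 to 0.906 over all lists. Fry, which tests a list against no change and not against other genes, called 0. Without deficient 5 camera called 5 lists, and without the library labelled heterozygous 4 it called 8. The list of oocyte growth and folliculogenesis had a median log2 fold change of -0.88 over 20 tested members, 16 of them negative (camera adjusted p = 0.00682, and adjusted p = 0.573 with an estimated correlation). No member passed over all genes, and 9 passed as lower when adjusted over the list alone. Of these, 1 is Taf4b, the gene that defines the genotypes, so its fall is no support for the list. Among the lower members were Sohlh1, Nobox, Lhx8 and Figla, transcription factors of the oocyte, Tle6, a component of the subcortical maternal complex, and Taf4b. Sohlh1, Nobox and Lhx8 were highest in the library labelled heterozygous 4 and heterozygous 5, where Hba-a1 was high as well. In deficient 5, with Hba-a1 at 590 CPM, Sohlh1, Nobox and Lhx8 were at 1.58, 5.36 and 19.9 CPM. Stra8, at 56.3 CPM in the library labelled heterozygous 4 and 10.3 CPM in heterozygous 5, was lowest there of all libraries. The same held for Rec8, a meiotic cohesin. The list's fall was not told apart from a difference of these heterozygous libraries in meiotic genes. By litter date, the list's level differed by -0.20, -0.72 and -1.56 on the log2 scale, and by level of the deposited grouping by -0.19, -0.41 and -1.12. The list's median was -0.40 without heterozygous 5, -0.34 with the deposited grouping in the model, -0.58 without the third litter date and -1.39 without the second level of the grouping, each still called, and -0.32 with the call lost (adjusted p = 0.0660) without the third level of that grouping. Tle6 was at 61.5 ± 53.5 CPM in heterozygous and 16.1 ± 8.87 CPM in deficient libraries.

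Chromatin modifiers had a median log2 fold change of 0.22 over 54 members, 37 positive (camera adjusted p = 0.00483, and adjusted p = 0.573 with an estimated correlation). Adjusted over the list alone, 9 passed as higher and 1 as lower, and over all genes none passed on genotype alone and 4 as higher with the deposited grouping in the model. Kmt2b, a histone methyltransferase, was at 34.4 ± 5.41 CPM in heterozygous and 69.3 ± 10.1 CPM in deficient libraries. Suz12, a subunit of the Polycomb repressive complex, was at 26.3 ± 4.09 and 51.6 ± 7.15 CPM, and the histone methyltransferase gene Dot1l at 56.5 ± 19.6 and 116 ± 15.4 CPM. Each of these was higher in 5 of 5 deficient libraries and called with the grouping (adjusted p = 0.0326), as was Ep300 (adjusted p = 0.0361). Kdm5a, the member with the highest mean, was at 544 ± 216 and 750 ± 173 CPM. The list's median was 0.12 (camera adjusted p = 0.0296) without deficient 3 and 0.09 (camera adjusted p = 0.0143) without the second litter date.

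Genes of primordial germ cells and pluripotency had a median log2 fold change of 0.55 over 23 members, 17 positive (camera adjusted p = 0.00562, and adjusted p = 0.573 with an estimated correlation), and none passed, also when adjusted over the list alone. Lin28b and Lin28a, RNA-binding proteins of immature germ cells, had log2 fold changes of 0.82 ± 0.22 and 1.55 ± 0.59 (SE), and Tcl1 one of -2.81 ± 0.88. By level of the deposited grouping the list's level differed by -0.22, 0.85 and 0.53, and its median was 0.87 without the first level and 0.28 with the call lost (adjusted p = 0.284) without the second.

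Pan-germ cell genes had a median of -0.36 over 27 members, 22 negative (camera adjusted p = 0.0171, and adjusted p = 0.573 with an estimated correlation), with none past the threshold in either adjustment. Ddx4 and Dazl, RNA-binding proteins of germ cells, were at 720 ± 129 and 1972 ± 449 CPM in heterozygous and at 551 ± 110 and 1701 ± 389 CPM in deficient libraries, and Sox30 had a log2 fold change of 0.66 ± 0.20. The call of the pan-germ cell list was lost without heterozygous 3 (median -0.22, camera adjusted p = 0.0636) and without deficient 5 (-0.26, adjusted p = 0.0761). Male fetal germ cell genes had a median of -1.06 over 6 members (camera adjusted p = 0.0434, and adjusted p = 0.573 with an estimated correlation). Of these, 4 passed as lower when adjusted over the list alone, Piwil4 among them at 9.76 ± 4.12 and 3.98 ± 1.69 CPM. Rhox13 was at 98.9 ± 62.4 and 69.0 ± 24.3 CPM. The level of this list, the median of its members' log2 CPM less each gene's mean over libraries, was 1.14 in the library labelled heterozygous 4 and 1.32 in heterozygous 5, against -0.17 to 0.12 in the other heterozygous and -0.47 to -0.13 in deficient libraries. Its call was lost without the library labelled heterozygous 4 (median -0.78, adjusted p = 0.139), heterozygous 5 (-0.70, 0.255), heterozygous 1, deficient 2, deficient 4 or deficient 5, without the third litter date (-0.58) or the third level of the deposited grouping (-0.24), and with a filter of 1 CPM in 5 libraries (-1.07), and with the deposited grouping in the model the median was -0.68 and still called. Apoptosis genes and p53 targets had a median of -0.27 over 27 members (camera adjusted p = 0.0361, and adjusted p = 0.573 with an estimated correlation), and 1 passed as lower when adjusted over the list alone, Pmaip1, at 21.9 ± 7.35 and 7.59 ± 3.24 CPM. Mdm2 was at 249 ± 54.4 and 206 ± 30.3 CPM. The call of this list was lost without heterozygous 1, heterozygous 2, heterozygous 3 (median -0.18), deficient 4 or deficient 5, with adjusted p from 0.0537 to 0.0842, with litter date in the model (-0.24, adjusted p = 0.116), without the first litter date (-0.27) and without the second level of the deposited grouping (-0.13).

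Lists of meiosis were not called by camera. Medians were 0.17 for meiotic entry, 0.11 for synaptonemal complex and meiotic cohesin, 0.05 for meiotic recombination and 0.07 for DNA damage response and repair, with adjusted p of 0.573, 0.151, 0.698 and 0.749. The synaptonemal complex and cohesin list was called higher without heterozygous 3 (median 0.26, adjusted p = 0.00780), and without the other single libraries its median ran from 0.04 to 0.24 and it was not called. The median of meiotic recombination was 0.26 without heterozygous 3 and turned to -0.09 without the library labelled heterozygous 4, -0.11 without heterozygous 5, -0.0091 without deficient 4 and -0.02 with the deposited grouping in the model. That of DNA damage response and repair turned to -0.0053 without the library labelled heterozygous 4 and -0.04 without heterozygous 5. Smc1b, a meiotic cohesin subunit, was at 1817 ± 518 CPM in heterozygous and 2190 ± 417 CPM in deficient libraries, M1ap at 2670 ± 3092 and 1423 ± 490 CPM, and Atr, a DNA damage kinase, at 434 ± 198 and 774 ± 286 CPM. For meiotic recombination the mean was -0.03, against the median's sign. TFIID subunits had a median of 0.02, while the camera statistic was negative (adjusted p = 0.897), and 1 member, Taf5, passed as higher when adjusted over the list alone. The TFIID median turned to -0.05, -0.04 and -0.03 without heterozygous 2, the library labelled heterozygous 4 and deficient 4. Taf5 was at 132 ± 58.6 and 277 ± 46.4 CPM and Taf7l at 1119 ± 326 and 1217 ± 226 CPM. Genes of premature ovarian insufficiency (median -0.22, adjusted p = 0.151) had 1 member higher and 5 lower when adjusted over the list alone, and the list was called lower without heterozygous 5 (median -0.21, adjusted p = 0.0291) and with the deposited grouping in the model (-0.21, adjusted p = 0.0476, and adjusted p = 0.485 with an estimated correlation). Its median was -0.07 (adjusted p = 0.473) without heterozygous 3, -0.11 with a filter of 1 CPM in 5 libraries and -0.14 with litter date in the model. Eif2b4, a translation initiation factor subunit, was at 63.5 ± 30.0 and 31.5 ± 2.57 CPM. Lars2 was at 2204 ± 1183 and 7100 ± 1881 CPM, and the noncoding Gm15564 ran from 32.5 to 258 CPM in heterozygous and from 335 to 616 CPM in deficient libraries. The noncoding Gm26917 did not part the genotypes, at 1084 to 7074 CPM in heterozygous and 6208 to 8242 CPM in deficient libraries. Heterozygous 3 was the lowest library for all 3 of these genes and for Gm24270, which were set side by side after their values were seen. They were compared as genes whose reads may come from ribosomal RNA, which was not tested here. The rise of Lars2 and Gm24270 may therefore not be one of their own transcripts.

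The remaining lists of cell function were not called. Medians were 0.22 for DNA methylation, -0.04 for general transcription and promoter factors, -0.23 for cell cycle and mitosis and -0.07 for oxidative phosphorylation, with camera adjusted p of 0.698, 0.905, 0.153 and 0.470. The median of general transcription factors turned to 0.03 without heterozygous 3, and that of oxidative phosphorylation to 0.0011 without heterozygous 5 and 0.0097 without deficient 3. With the deposited grouping in the model the medians of DNA methylation and general transcription factors were 0.07 and -0.08, neither of them called. Uhrf1, which maintains DNA methylation and was the only member of its list to pass when adjusted over the list alone, was at 212 ± 61.4 CPM in heterozygous and 108 ± 29.2 CPM in deficient libraries. Polr2a, the large subunit of RNA polymerase II, was at 203 ± 38.2 and 314 ± 69.1 CPM, Polr2b at 593 ± 251 and 475 ± 114 CPM, Sp1 at 48.4 ± 11.0 and 72.2 ± 11.3 CPM, and Nfyb at 41.7 ± 22.1 and 18.7 ± 7.53 CPM. Of 35 cell cycle genes, 25 were negative and 10 positive, 8 lower and 1 higher at an unadjusted p under 0.05, and none passed when adjusted over the list alone. The list was called lower without heterozygous 5 (median -0.26, adjusted p = 0.0239) and with the deposited grouping in the model (-0.21, adjusted p = 0.0464, and adjusted p = 0.641 with an estimated correlation). Its median was -0.03 without heterozygous 3, -0.13 without deficient 5, -0.15 without deficient 2 and -0.07 with litter date in the model, and none of these was called. Mki67 was at 84.8 ± 37.2 and 173 ± 45.2 CPM (adjusted p = 0.0326 with the deposited grouping) and Bub1 at 631 ± 294 and 792 ± 194 CPM, while Plk1 was at 40.4 ± 10.2 and 22.4 ± 9.96 CPM and Ccnb2 at 227 ± 112 and 108 ± 47.3 CPM. Atp5a1, an ATP synthase subunit, was at 659 ± 86.6 and 426 ± 24.9 CPM, lower in 5 of 5 deficient libraries, and Ndufa1 at 1954 ± 423 and 1822 ± 454 CPM.

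**Figure D4:**
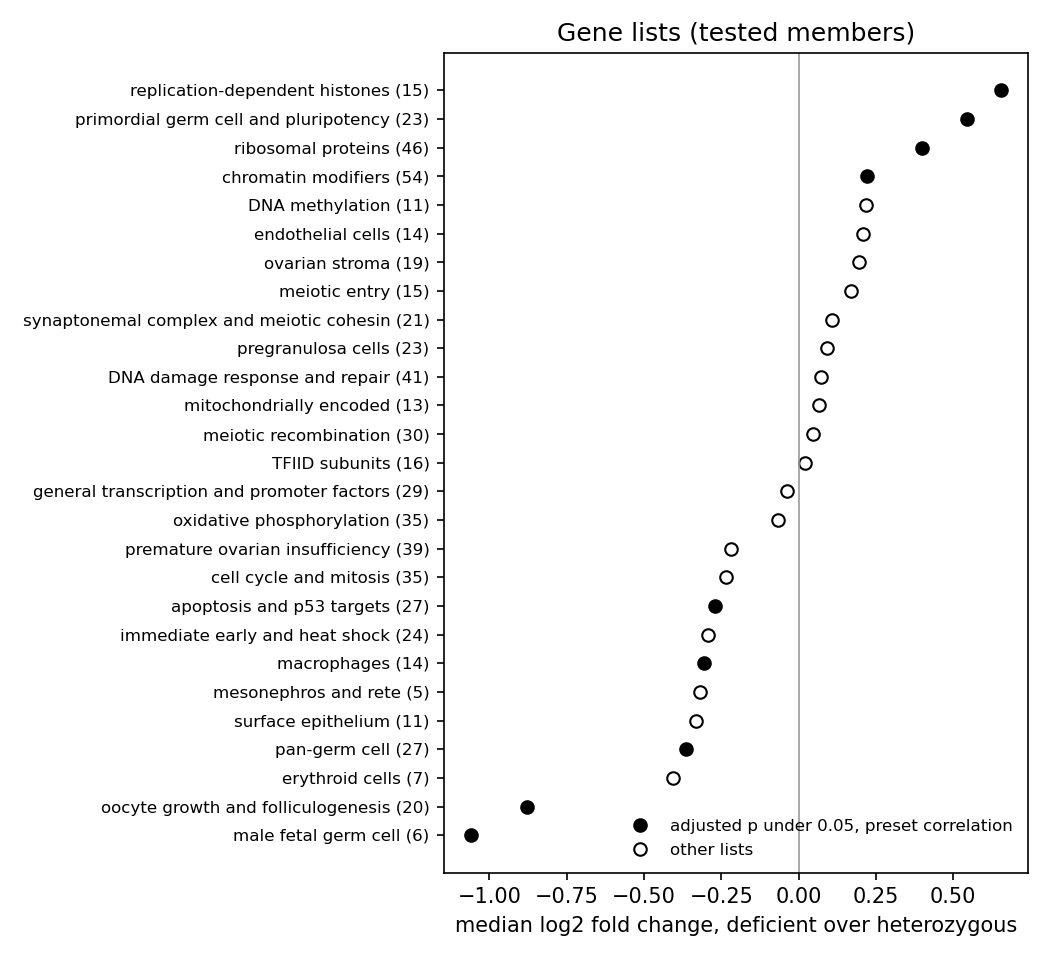
Median log2 fold change (deficient over heterozygous) of the tested members of each gene list, with the number of members in brackets; filled points are the 9 lists called by camera with the preset correlation. With an estimated correlation 0 lists were called.

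Among the lists of library quality, ribosomal protein genes had a median log2 fold change of 0.40 with 44 of 46 members positive (camera adjusted p = 2.05e-07, and adjusted p = 0.732 with an estimated correlation), and replication-dependent histones one of 0.65 (camera adjusted p = 0.000459, and adjusted p = 0.592 with an estimated correlation). Of these, 1 histone gene, Hist1h1a, passed as higher when adjusted over the list alone, at 5.69 ± 1.99 CPM in heterozygous and 16.0 ± 2.46 CPM in deficient libraries, and was called over all genes with the deposited grouping (adjusted p = 0.0352). Hist1h1e and Hist1h1b had log2 fold changes of 0.93 ± 0.33 and 0.78 ± 0.30, Hist1h4d 0.65 ± 0.39, and Rpl30, Rpl12, Rps4x and Rpl4 had 1.17, 0.61, 0.77 and 0.31. By litter date the level of ribosomal proteins differed by 0.26, 0.81 and 0.13 and that of histones by 0.35, 0.86 and 0.69, and by level of the deposited grouping by 0.13, 0.85 and 0.36 and by 0.49, 1.09 and 1.26. The ribosomal protein level of heterozygous 3 was -1.21, and without this library the median was 0.22 (camera adjusted p = 0.00181). Without the second litter date or the second level of the grouping the ribosomal protein median was 0.24, and without the third litter date that of histones was 0.24, each still called. Mitochondrially encoded genes (median 0.07, adjusted p = 0.375) and immediate early and heat shock genes (median -0.29, adjusted p = 0.106) were not called. The former were called higher without heterozygous 5 (median 0.23, adjusted p = 0.0202) and with the deposited grouping in the model (0.34, adjusted p = 0.0476, and adjusted p = 0.799 with an estimated correlation), while their median turned to -0.19 without heterozygous 3, -0.17 without deficient 5, -0.05 without heterozygous 2 and -0.02 with litter date in the model. The latter were called lower without heterozygous 2 (-0.36), heterozygous 3 (-0.30) or deficient 3 (-0.39), and their median was -0.17 (adjusted p = 0.285) without heterozygous 5, -0.18 (adjusted p = 0.208) without deficient 2 and -0.17 (adjusted p = 0.153) with the deposited grouping in the model. Hsp90aa1, mt-Co1 and Jund had log2 fold changes of 0.33 ± 0.24, 0.14 ± 0.29 and 1.41 ± 0.50.

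Of the markers of other cell types, macrophage genes were called lower, with a median of -0.30 and 13 of 14 negative (camera adjusted p = 0.0291, and adjusted p = 0.732 with an estimated correlation). Lyz2 was at 72.2 ± 30.3 CPM in heterozygous and 65.5 ± 25.1 CPM in deficient libraries, and C1qc, Cd68 and Csf1r had log2 fold changes of -0.47 ± 0.24, -0.44 ± 0.25 and -0.52 ± 0.37. The macrophage call was lost without heterozygous 1 (median -0.16, adjusted p = 0.170), heterozygous 2 (-0.27, 0.0550), deficient 3 (-0.19, 0.0692) or deficient 5 (-0.13, 0.395), with litter date in the model (-0.16, 0.233), without the first or the third litter date (-0.22 and -0.14) and without the second or the third level of the deposited grouping (-0.26 and -0.22). The median was -0.60 with the deposited grouping in the model, -0.57 without its first level and -0.49 without the second litter date, each still called. Pregranulosa cells, ovarian stroma, surface epithelium, endothelial cells, erythroid cells, and mesonephros and rete had medians of 0.09, 0.20, -0.33, 0.21, -0.41 and -0.32, with adjusted p of 0.698, 0.698, 0.749, 0.470, 0.698 and 0.698. The endothelial median was 0.68 and called without heterozygous 5 (adjusted p = 0.0273), -0.24 without deficient 1 and -0.0031 without heterozygous 3. That of erythroid cells turned to 0.50 without heterozygous 5 and to 0.25 with the deposited grouping in the model and was -1.98 without deficient 5, that of pregranulosa cells lay between -0.10 and -0.0093 without heterozygous 1, heterozygous 3, deficient 3 or deficient 5, that of ovarian stroma was -0.02 without heterozygous 3 and -0.0068 without deficient 1, and that of surface epithelium was 0.07 with the deposited grouping in the model. Foxl2 and Fst, of pregranulosa cells, were at 1.08 ± 0.82 and 2.92 ± 2.07 CPM in heterozygous and at 2.74 ± 2.05 and 6.84 ± 3.16 CPM in deficient libraries. Col3a1 was at 22.2 ± 16.2 and 32.2 ± 31.6 CPM, Col1a2 at 3.95 ± 1.66 and 7.57 ± 4.204 CPM, Aldh1a2 at 28.0 ± 6.16 and 21.3 ± 4.21 CPM, Plvap at 10.6 ± 1.88 and 11.5 ± 3.02 CPM, Cdh5 at 1.86 ± 2.13 and 3.13 ± 2.46 CPM, and Epcam at 55.7 ± 25.2 and 68.1 ± 10.5 CPM.

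With whole litter dates or levels of the deposited grouping left out, some of the lists not called over all libraries were called. Without the third level these were meiotic recombination (-0.13), premature ovarian insufficiency (-0.27), cell cycle and mitosis (-0.24), mitochondrially encoded genes (0.48) and endothelial cells (1.04). Without the second level they were synaptonemal complex and meiotic cohesin (0.35), oxidative phosphorylation (-0.14) and immediate early and heat shock genes (-0.51). Without the third litter date they were cell cycle and mitosis (-0.25) and endothelial cells (0.76), and without the second date immediate early and heat shock genes (-0.30). Endothelial genes had medians of -0.48 without the first date and -0.30 without the first level, and mitochondrially encoded genes of -0.20 without the second level, none of them called.

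X-linked genes were compared with autosomal genes as a set. Female germ cells reactivate the silent X chromosome during fetal life. The median log2 fold change was -0.136 for 769 X-linked and -0.00929 for 18340 autosomal genes, and 62.8% against 50.7% were negative. Camera gave p = 0.0177 with the preset correlation and p = 0.114 with an estimated correlation. Fry, which compares the X-linked genes with no other genes and so does not test this difference, did not call them. Without the library labelled heterozygous 4 the difference between the medians was -0.090, from -0.127 with it, and without the third level of the deposited grouping it was -0.069 and no longer called, against -0.192 without the second level. By litter date, the X-linked shift was -0.03, -0.16 and -0.17 on the log2 scale, and by level of the deposited grouping -0.05, -0.03 and -0.21. Among the 104 genes called by edgeR with the deposited grouping, 8 X-linked genes were lower and 1 higher, against 25 autosomal genes lower and 70 higher, and X-linked genes were called lower more often than autosomal genes among those tested (odds ratio 7.70, Fisher's exact two-sided p = 3.76e-05). That test counts genes as independent, which they are not, and rests on the 8 lower X-linked genes. For the X-linked genes as a set in the same fit, camera gave p = 0.0141 with the preset correlation and p = 0.161 with an estimated correlation. The authors' deposited table calls 55 X-linked genes lower and 11 higher. Xist, which silences the X chromosome, was at 19.4 ± 12.7 CPM (SD, n = 5) in heterozygous and 24.7 ± 10.4 CPM (SD, n = 5) in deficient libraries.

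The median X-linked TPM over the median autosomal TPM was 0.939 ± 0.084 (SD, n = 5) in heterozygous and 0.859 ± 0.030 (SD, n = 5) in deficient libraries. The difference of -0.080 did not pass a two-sided exact permutation test (p = 0.0635, with 0.00794 the smallest p that 252 assignments allow), although without heterozygous 3 it was -0.102 with an exact p of 0.0238. It was -0.053 (exact p = 0.159) without heterozygous 5, -0.147 (exact p = 0.10) and -0.021 (exact p = 0.486) without the second and the third level of the deposited grouping, and -0.049 (exact p = 0.143) with means in place of medians. By litter date the differences were -0.062, -0.074 and -0.169, and by level of the deposited grouping -0.087, 0.020 and -0.177. Among genes with a TPM of at least 5 the difference was 0.00231 (exact permutation p = 0.952), and among all genes with a TPM above 0 it was -0.117 (exact permutation p = 0.00794). The library labelled heterozygous 4 and heterozygous 5 had the highest ratios, 0.998 and 1.05.

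**Figure D5:**
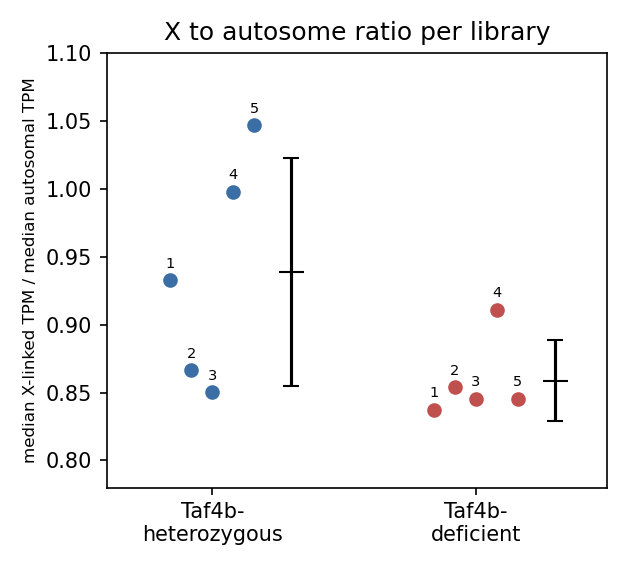
Median X-linked TPM over median autosomal TPM (genes with a TPM of at least 1) per library and genotype, on an axis that does not start at 0; points are libraries, numbered by replicate, and bars are the mean with SD of 5 libraries. Heterozygous libraries run from 0.850 to 1.05 and deficient libraries from 0.837 to 0.911.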

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

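Within each genotype, the highest or lowest of 5 libraries was marked where its gap to the next library exceeded 0.71 of the group's range, over 81 measures (the named genes in CPM, the X to autosome ratio and the total count). Were the values independent and normally distributed, chance would mark about 1 in 20 groups, 8.1 of 162. In these data 14 were marked, 9 of them in deficient 5. Genes vary together, so setting 14 against 8.1 is no test of chance. Deficient 5 was the highest deficient library for Hba-a1 at 590 CPM (others up to 91.4), Hist1h1e at 175 CPM, Plk1 at 40.01 CPM, Ccnb2 at 190 CPM, Tle6 at 31.5 CPM, Gm13269 at 11.5 CPM, C87487 at 4.44 CPM and Gm11815 at 0.572 CPM, and the lowest for M1ap at 568 CPM (others from 1496). Deficient 3 was highest for Polr2b at 678 CPM, and deficient 4 for the X to autosome ratio at 0.911. Heterozygous 1 was highest for Rhox13 at 209 CPM, and heterozygous 3 for Eif2b4 at 116 CPM and Plvap at 13.8 CPM.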

How the results depend on the processing

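Surrogate variables, the deposited grouping and bias-adjusted deviances were chosen after the data were seen. The cause of each change below was not tested, and some fits held fewer libraries or genes. The count of called genes, 0, was 251 with no filter on low counts, 643 by DESeq2, 510 by limma voom with quality weights, 104 with the deposited grouping and 3 with bias-adjusted deviances, and it stayed at 0 under the other 14 settings; without single libraries it ran from 0 to 606, with 606 without heterozygous 1 and 1 without heterozygous 2. With the replicate block it was 1; the numbers share only a number, since same-numbered libraries correlated between -0.262 and 0.593 and 1 of 5 heterozygous libraries correlated best with its own number. Taf4b was lower under every setting (-1.83 to -0.48) and passed with no filter (-1.24, adjusted p 0.0408), DESeq2 (-1.23, 0.0350) and the deposited grouping (-1.28, 0.0361), of adjusted p from 0.0350 to 0.961; single libraries left out gave -1.42 to -0.95. The 9 lists became 0 with an estimated correlation, alone and with the deposited grouping, and fry, which compares a set with no other genes and so does not test these differences, called 0; they were 5 to 12 without single libraries, with 5 without deficient 5. The X-linked difference of -0.127 kept its direction and lost its call with an estimated correlation (-0.127), with the deposited grouping and an estimated correlation (-0.091) and without the third level of that grouping (-0.069), and ran from -0.189 to -0.090 without single libraries. The X to autosome difference was -0.117 (p = 0.00794, exact permutation) at TPM above 0 and 0.00231 at TPM of at least 5, and -0.102 to -0.053 without single libraries. With the same genes in every library it was -0.078 (p = 0.206, exact permutation). The 1172 calls of the authors' deposited table are 405 at an adjusted p under 0.01 and 386 with an absolute log2 fold change of at least 1. Of 77 named genes besides Taf4b, edgeR on genotype alone called none, and 27 were called by DESeq2, 25 by voom with quality weights, 22 with no filter, 16 with the deposited grouping, 26 without heterozygous 1, and 1 each with bias-adjusted deviances (Trim52) and the replicate block (Gm11815). With that block the synaptonemal complex list was called (0.26, adjusted p 0.0434), the medians of oocyte growth and pan-germ cell were -0.52 and -0.22, and those of general transcription (0.022), oxidative phosphorylation (0.0074) and pregranulosa cells (-0.0055) turned. Log2 fold changes turned in sign as follows. With 2 surrogate variables: Epcam -0.34, Hba-a1 1.63, Hist1h4d -0.22, Hsp90aa1 -0.0070, Mdm2 0.046, Taf7l -0.38 and mt-Co1 -0.18. With the deposited grouping: Hba-a1 0.25. Without its first level: Plvap -0.023. Without the second level: Ces1c -0.23, Col3a1 -0.19, Polr2b 0.0016, Taf7l -0.056 and mt-Co1 -0.024. Without the third level: Hba-a1 0.12, Lyz2 0.40 and Plvap -0.0098. On log2 TPM: Plvap -0.0089 with 0.1 added and -0.0032 with 1 added, filtered or not. By voom with quality weights: Ces1c -0.33, Col3a1 -0.59, Lyz2 0.022 and M1ap 0.62. With litter date: Ces1c -0.76. Without the first litter date: Cdh5 -0.33, Ces1c -0.00032 and Plvap -0.073. Without the second date: Taf7l -0.057. Without the third date: Cdh26 -0.40, Ces1c -1.09, Lyz2 0.20 and Pamr1 -0.42. With the replicate block: M1ap 0.076. Without single libraries the range crossed 0 for M1ap (-1.22 to 0.029), Ndufa1 (-0.23 to 0.018), mt-Co1 (-0.045 to 0.24), Col3a1 (-0.16 to 0.95), Plvap (-0.016 to 0.23), Hba-a1 (-2.06 to 0.64), Lyz2 (-0.29 to 0.14) and Ces1c (-0.51 to 1.09).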

Other observations

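The chance splits of the libraries for unadjusted p-values, lists and X-linked genes, those within the deposited grouping for called genes, lists and X-linked genes, and the length, GC content and gene family tests were set before their results were seen; the other tests were chosen afterwards. Gene symbols here were chosen after their values were seen, unless the rule names them.

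Rec8, a meiotic cohesin, was at 49.7 CPM in heterozygous 1 and 2.34 CPM in heterozygous 5, and from 11.0 to 53.1 CPM in deficient libraries. Lhx8, an oocyte transcription factor, was at 213 CPM in heterozygous 5, 85.7 CPM in the library labelled heterozygous 4 and 8.56 to 14.4 CPM in the other heterozygous libraries, and Uchl1 at 171, 85.1 and 5.66 to 10.4 CPM. In deficient 5, where Stra8 was at 156 CPM, below the other deficient libraries, Lhx8 was at 19.9 CPM and Uchl1 at 7.12 CPM. Sycp3, of the synaptonemal complex, ran from 588 to 1802 CPM among heterozygous and from 690 to 969 CPM among deficient libraries.

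The genotype comparison was repeated on 100 splits of the 10 libraries into 5 and 5, with the real split counted among them. As 0 genes were called, all 100 splits give as many by construction, so that count is no test of chance. The highest other split called 1601, with heterozygous 1 and deficient 1 to 4 on one side. It is the real split with heterozygous 1 and deficient 5 exchanged, so most libraries stay with their genotype. Whether its calls follow genotype or another structure of the libraries cannot be told apart. For unadjusted p under 0.05, 8 of 100 splits gave as many as the 3190 genes (highest other 5328), and for gene lists 49 of 100 gave as many as the 9 lists (highest other 14), so chance is not excluded for either over splits that set the grouping aside. With the deposited grouping in the model, 54 splits keep the genotype numbers in each of its levels. Of these, 1, the real one, gave as many as the 104 genes called (highest other 0). For the 3612 genes with an unadjusted p under 0.05, 1, again the real one, gave as many (highest other 2320). A share of 1 in 54 is the smallest that these splits allow. It argues against chance for both counts within the grouping. The grouping was chosen after the data were seen, so chance is not excluded. For gene lists 8 of the 54 gave as many as the 12 lists called in that model (highest other 14), and chance is not excluded.

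The authors' deposited fold changes are rebuilt by a grouping that matches the litter dates of the labels in 6 of 10 libraries. Laid in label order on the columns in the order of the count table, the dates match it in 10 of 10. The grouping explained 49.9% of the variance between libraries left after genotype, above all 100 random groupings (highest 45.5%), and the dates of the labels explained 28.3%, with 39 of 100 random groupings as high. This argues against a grouping set on the wrong libraries in the deposited model, and is consistent with litter dates set against other libraries than their own in the labels. No biological explanation was tested.

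The low Taf4b of the library labelled heterozygous 4 may come from a wrong genotype label or from fewer germ cells in the sort. A difference between oocytes of this genotype, or one that goes with the third level of the deposited grouping, was not tested. By level, Taf4b was at 271, 216 and 83.3 CPM in heterozygous and at 81.2, 76.9 and 58.2 CPM in deficient libraries. Each value is from 1 or 2 libraries, and this library is in the third level. Fewer germ cells would lower all germ cell genes alike, but the median of 27 pan-germ cell genes differed from the other heterozygous libraries by -0.32 on the log2 scale, against -1.48 for Taf4b. This argues against it as the whole cause. Of the 27 genes, 15 were lower, with a scaled median absolute deviation of 0.63. The levels of other cell types lay above those of heterozygous 1, 2 and 3, for example 1.42 for erythroid and 0.60 for pregranulosa cells, except macrophages (0.16). More RNA of other cells is thus not excluded as part of the cause. Of 100 genes picked in the other 9 libraries, 93 lay nearer the heterozygous mean in this library, and 92 with the deposited grouping taken out. The same scores were 14 and 9 for heterozygous 1, whose Taf4b was at 271 CPM, so they follow more than the Taf4b genotype, and a wrong label cannot be told apart from a correct one with them. Heterozygous 1, left out, is also the library without which edgeR called 606 genes.

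For the lower median of X-linked genes, length and GC content were tested as a trend over autosomal genes. The difference from autosomal genes was -0.127 before and -0.166 after that trend was removed, and -0.124 without 197 X-linked genes of multicopy families or with predicted-gene symbols, which argues against both as the whole cause. Chance is not excluded: 7 of 100 splits gave a difference as large as 0.127 in either direction, the highest other 0.158, and within the deposited grouping 7 of 54 gave one as large as 0.091, the highest other 0.124. An effect of genotype on X-linked genes stays a hypothesis, and without the third level of the deposited grouping the difference was -0.069 and the call was lost.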
